A study of Mus musculus with 38 samples.

How the data were processed

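The 38 libraries are 10x 5′ single-cell RNA libraries, each made from 1 sample: 36 kidney tumours of male mice with inducible deletion of Vhl, Trp53 and Rb1 in kidney epithelium, and 2 normal kidneys. Per the labels, tissue was minced and digested for 25 min at 37 °C, red cells were lysed, live single cells were sorted, and up to 10000 cells were loaded; 1 normal kidney was mixed from CD45-positive and CD45-negative cells at 4:1. Per the labels, lenvatinib was given by mouth at 8 mg/kg on 5 to 7 days per week, anti-PD-1 at 100 µg and the CSF1R inhibitor at 200 mg/kg, for about 2 weeks or long term; the labels give each tumour a response group without saying how response was judged. The labels form 16 groups and give a sequencing batch letter for each library (I, O, Q, S or U).

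The authors deposited, for each library, a matrix of UMI counts per gene and cell barcode, with lists of barcodes and genes as non-measurement files. Per the labels and the matrix headers, Cell Ranger made them on mm10, and the headers name software version 3.0.2. All matrix values are whole numbers without normalization. The read filters and the rule that called cells are not given in the sources used here. Every library lists the same 31053 genes, of which 30934 have a position in the GENCODE vM21 annotation used here for coordinates. Genes are named by the symbols of the deposited lists.

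Of 272773 barcodes, 266383 with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept (84.6 to 99.8% per library). Scrublet, run with scanpy 1.11.5 and an expected rate of 0.06, ranked likely doublets, and 0.8% of cells per 1000 cells of the library were removed (19675 cells, 7.39%), which left 246708. Counts were scaled per cell and log-transformed. The 2000 most variable genes and 40 principal components were chosen on 1000 cells per library so that libraries weigh alike, and all cells were placed on them. Leiden clustering (igraph 0.11.9, 15 neighbours, Jaccard weights, resolution 1.5, no batch integration) gave 82 clusters. Clusters were named from marker lists fixed beforehand. A cluster with a second lineage score above 2.5 that lay within 3 of the first stayed unnamed. Clusters of renal epithelium were split by library origin, not by markers. They were called normal where at least 50% of their cells came from normal kidneys, and carcinoma otherwise. Of 17 carcinoma clusters 8 took more than 50% of their cells from 1 library, of 12 macrophage clusters 3, of 6 T cell clusters 1, and endothelial cells formed 1 cluster. One cluster of mixed epithelial and mesenchymal genes stayed unnamed, and 1 carcinoma cluster led by tubule markers was kept as carcinoma. Largest clusters are of cells pooled over a group's libraries, so libraries with many cells weigh most.

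Libraries held 1548528 to 134314238 UMIs and 519 to 13316 analysed cells, with medians of 1441 to 7735 UMIs and 750.5 to 2791.5 genes per cell. By group the UMI ranges were 9931241 to 54473623 for untreated tumours (4 libraries), 8448357 to 27132109 for lenvatinib 2-week responders (4), 20915804 to 86898296 for lenvatinib acquired non-responders (6), 1548528 to 57929595 for lenvatinib plus anti-PD-1 responders (4), 27607619 to 134314238 for anti-PD-1 2-week responders (3), 68456640 to 124214212 for the matching non-responders (3), 33397560 to 57639602 for anti-PD-1 partial responders (3) and 47439893 to 60070743 for CSF1R inhibitor alone (3). The normal kidneys held 54874530 and 14869115 UMIs. Carcinoma cells were few in anti-PD-1 2-week responder replicates 2 (33 cells) and 3 (59) and lenvatinib responder replicate 1 (64). Acquired non-responder replicate 1 (13 cells) and combination responder replicate 4 (5 cells) were left out of carcinoma tests. Counting intervals are 95% Poisson limits, or exact binomial limits for ratios of pooled counts, and a group at 0 is set at 3 counts over the group.

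Counts were summed per class and library where the class had at least 20 cells. edgeR 4.0.16 (R 4.3.3) fitted group plus batch over all tumour libraries together, with filterByExpr, TMM factors and robust quasi-likelihood F tests; log2 differences carry standard errors, and CPM means carry SDs over libraries. Adjusted p values are Benjamini-Hochberg over the genes of one comparison, two-sided, with a threshold of 0.05. Of the 40 gene lists written beforehand, 22 hold programs and 18 hold markers. A list needed 5 tested members. Camera of limma 3.58.1 compared its members with all other genes at a preset correlation of 0.01 and again with the correlation estimated from the data; fry asks whether members move one way on balance and compares them with no other genes. Shares of cells were compared by exact permutation over all splits, two-sided, and adjusted over 96 tests. The comparisons, lists and rule for named genes were chosen before the data were examined. Normal kidneys and groups of 1 or 2 libraries were given as values only, except that the 3 tumours under CSF1R inhibitor alone were joined. Correlations between comparisons that share a control group were not computed.

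The text names up to 5 rising and 5 falling genes past the threshold with a mean of at least 20 CPM over the compared samples, ordered by size of change, up to 3 of smallest p in a direction where fewer than 5 pass, up to 4 members of each shifted program list, and genes chosen for the study's question. Ribosomal, mitochondrial, immunoglobulin and T cell receptor genes, unnamed gene models and markers of other classes are left out; in carcinoma cells of acquired non-responders against responders this removed 13 called genes by type and the marker gene Apoe, and in macrophages 7. The rule was fixed beforehand, and the limit of 30 genes per comparison and class was set after values were seen. Of the genes it gives, some are not named, for length. One gene it gives is not reported here. The labels do not say which exons are deleted, and a 5′ tag may lie outside them, in which case targeted genes check nothing.

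The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, no batch term, at least 50 cells, kept doublets, at most 10% mitochondrial UMIs, shares outside carcinoma cells or in shared batches, an edgeR test of cell counts, fits of the compared groups alone, a replicate block, and each library left out in turn. Added after the data were seen were fits within 1 batch, a Leiden resolution of 3 for gene and share results (for cell classes it was planned), shares of named cells, at least 10 cells for endothelial cells, and fits without the libraries in doubt, with the unnamed mesenchymal cluster, or without the tubule-led cluster. Other splits of the samples were limited to 60 per comparison. Whether replicate numbers pair samples across groups was checked on 2000 variable genes, and no class and comparison had all pairs correlated above 0.1. No 2 libraries of a group were duplicates: over 44 pairs, chi-square per degree of freedom was 33.2 to 1053.

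The fits were tested on simulated data. False calls there may understate those on real data, where other splits gave up to 282 genes. Of genes changed 2-fold and 8-fold, 9% and 99% were called in carcinoma cells of lenvatinib responders against untreated tumours (16029 genes), 47% and 100% in macrophages of acquired non-responders against responders (13361 genes), 1% and 40% in endothelial cells (7723 genes) and 33% and 100% in T cells of combination against lenvatinib responders (10599 genes), with 0, 7, 0 and 3 unchanged genes called. The share test called 2.6% of 500 simulations without a shift and 99.6% with a shift of 30 points. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.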

Results

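Single-cell 5′ transcriptomes of 36 treated or untreated kidney tumours and 2 normal kidneys of male mice left 246708 cells after filtering, and 91.4% of them fell into 12 named cell classes. Macrophages (61340 cells, monocytes included), carcinoma cells (56165), neutrophils (46833) and T cells (22225) were the largest, and endothelial cells numbered 1976. Of the neutrophils, 1950 lay in a cluster with neutrophil markers but led by monocyte genes such as Ear2 and Treml4, so their name is uncertain. Untreated tumours (n = 4) held 38.3 ± 17.0% carcinoma cells, 27.9 ± 14.9% macrophages, 8.22 ± 3.42% neutrophils, 5.68 ± 3.19% T cells and 1.42 ± 0.56% endothelial cells (mean ± SD). The normal cortex (n = 1) held 92.8% normal kidney epithelium, 2.29% macrophages, 0.76% T cells and 0.794% endothelial cells. Carcinoma clusters held 0.182% of its cells. Epithelial clusters were split into normal and carcinoma by library origin, so these epithelial values are largely set by that rule. The other normal kidney, mixed at 4 CD45-positive cells to 1 CD45-negative cell, held 23.6% macrophages, 23.3% normal epithelium and 17.2% T cells. All shares are of sorted live single cells after dissociation, so they measure what survived those steps. Most cells had no name in anti-PD-1 2-week non-responder replicate 3 (58.2%) and in the long-term CSF1R inhibitor tumour (52.4%), which limits their shares.

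Per the labels, tumours arise by deletion of Vhl, Trp53 and Rb1. Vhl (chromosome 6, 113623959–113631633) encodes the ubiquitin ligase subunit that marks hypoxia-inducible factors for degradation. Its median over 34 libraries was 0.55 CPM in carcinoma cells (range 0 to 3.38). The median was 19.8 CPM in macrophages (38 libraries, 9.16 to 31.8) and 16.1 CPM in T cells. Normal epithelium of the cortex held 11.7 CPM (95% counting interval 10.7 to 12.8). The tumour suppressor Trp53 (chromosome 11, 69580359–69591873) had medians of 18.5 CPM in carcinoma cells (6.13 to 53.0) and 75.1 in macrophages (37.5 to 111). Rb1 (chromosome 14, 73183673–73325822), which restrains entry into the cell cycle, had medians of 10.8 CPM in carcinoma cells (2.93 to 41.7) and 50.7 in macrophages (16.8 to 99.0). These values were not tested, and a 5′ tag can lie outside the deleted part.

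The first question was what lenvatinib, an inhibitor of VEGF and FGF receptors, leaves in carcinoma cells of tumours that respond at 2 weeks (n = 4) compared with untreated tumours (n = 4). The transcription factor gene Runx1 stood at 57.3 ± 28.9 against 17.1 ± 14.4 CPM (log2 difference 3.02 ± 0.60, SE). Gstp2, a glutathione transferase gene (chromosome 19, 4040285–4046023), was nearly silent in responders, at 0.513 ± 0.51 against 124 ± 75.3 CPM (-8.54 ± 1.66). The basal transcription factor gene Gtf2b stood at 43.4 ± 4.81 against 89.3 ± 31.8 CPM (-1.25 ± 0.23). The edgeR adjusted p was 0.068 for each of these 3 genes, and 0 of 17048 genes passed 0.05. The unadjusted p was under 0.05 for 3466 genes, and DESeq2 called 1182. Leaving out untreated replicate 3 gave 55 calls and leaving out responder replicate 3 gave 5. Batch I, with all 4 responders and 2 untreated tumours, gave 10, among them Gstp2 (log2 -7.76, adjusted p = 0.00372). Other batches held no such responder. The HIF targets Car9 (158 ± 9.32 against 223 ± 106 CPM, adjusted p = 0.304) and Vegfa (285 ± 58.9 against 197 ± 115 CPM, adjusted p = 0.351) did not separate the groups. The largest clusters were 22 in responders (68.4%) and 10 in untreated tumours (26.1%). Responder replicate 2 gave 1908 of the 2765 pooled responder cells.

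By camera, 8 of 35 gene lists shifted in these carcinoma cells. The nuclear RNAs Malat1 (11219.7 ± 3702 against 2691 ± 1330.0 CPM) and Neat1 (726 ± 312 against 154 ± 64.9 CPM) stood higher in the same responder libraries, a sign of RNA quality or nuclear RNA that moves with the group. Cell-cycle genes were lower (27 of 28 members, median log2 -0.74, adjusted p = 0.000179; adjusted p = 0.681 with an estimated correlation). Examples are Cdk1, the kinase that drives mitotic entry (22.1 ± 4.86 against 72.0 ± 46.3 CPM, lower in 4 of 4), and Birc5 (33.9 ± 6.96 against 86.7 ± 27.5 CPM). Oxidative phosphorylation genes were lower (18 of 20, median -0.69, adjusted p = 0.00147; 0.681 with an estimated correlation), among them the complex I gene Ndufa5 at 160 ± 74.1 against 384 ± 105 CPM. Both lists kept their side of the threshold without any 1 library. Glycolysis genes were lower (15 of 17, median -0.63, adjusted p = 0.0108; 0.681 with an estimated correlation), with Ldha, the lactate dehydrogenase gene, at 2768 ± 759 against 4446 ± 1151 CPM. Without untreated replicate 3 the list's adjusted p was 0.0501. Inflammatory cytokine and NF-kB genes were higher (15 of 20, median 1.16, adjusted p = 0.0114; 0.681 with an estimated correlation), with the NF-kB inhibitor gene Tnfaip3 at 50.1 ± 10.8 against 26.4 ± 10.5 CPM in 4 of 4 responders. Without untreated replicate 3 that p was 0.285. Adjusted over the list alone, 2 cell-cycle genes passed, against 0 over all genes.

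Acquired non-response was compared with early response to lenvatinib in carcinoma cells of 5 acquired non-responders and 4 responders. Of 17048 genes 191 rose and 675 fell. The homeobox gene Rhox6 (X, 37826910–37829857) rose from 0.136 ± 0.271 to 94.97 ± 35.03 CPM (adjusted p = 0.0168), higher in 5 of 5. The responders held 1 count in all, so the ratio of pooled counts, 1803, has a counting interval of 323 to 71224. Its neighbour Rhox5 (X, 37804842–37808876), at 0 CPM in all 4 responders, stood at 89.2 ± 98.8 CPM, at least 522-fold higher than a floor of 3 counts over the group (0.171 CPM; adjusted p = 0.0375). Gstp2 rose to 77.6 ± 39.9 CPM (7.09 ± 1.55, adjusted p = 0.0142). The long noncoding RNA Snhg11 rose from 1.11 ± 1.90 to 62.5 ± 70.2 CPM (7.13 ± 1.63, adjusted p = 0.0175). Arglu1, a splicing regulator gene (chromosome 8, 8665075–8690521), fell from 202 ± 61.5 to 47.3 ± 33.8 CPM (-2.84 ± 0.52, adjusted p = 0.00649), lower in 5 of 5. Rb1 fell from 20.2 ± 11.4 to 7.07 ± 5.18 CPM (-2.06 ± 0.41, adjusted p = 0.00821). The VEGF gene Vegfa fell from 285 ± 58.9 to 135 ± 52.1 CPM (-1.31 ± 0.36, adjusted p = 0.0354), lower in 5 of 5. The ephrin ligand gene Efnb2 fell from 43.1 ± 29.7 to 9.50 ± 9.35 CPM (-3.04 ± 0.69, adjusted p = 0.0153). The change of Vhl from 1.88 ± 0.919 to 0.709 ± 0.24 CPM did not pass (adjusted p = 0.155).

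Arglu1 and Rb1 kept their call in this comparison without any 1 library. Gstp2 lost it without responder replicate 4 (adjusted p = 0.0554), Rhox6 without responder replicate 2 (0.0548) or 4 (0.0654), and Efnb2 without acquired non-responder replicate 6 (0.0594). Snhg11 lost it without acquired non-responder replicate 2 (0.0737) or responder replicate 2 (0.055) or 4 (0.0704). Vegfa lost it without acquired non-responder replicate 2 (0.108), 4 (0.0917) or 6 (0.104) or responder replicate 1 (0.066), 2 (0.0842) or 4 (0.0568). Rhox5 lost it without acquired non-responder replicate 2 (0.0976), 4 (0.0651) or 6 (0.0652), or without responder replicate 1 (0.0612), 2 (0.0783), 3 (0.0637) or 4 (0.0938). The total of 866 fell to 207 without acquired non-responder replicate 2, 236 without 6, 369 without 4, 353 without responder replicate 4, 494 without 1 and 566 without 2. DESeq2 called 2149 genes, 852 of them shared. Batch I alone, with 3 acquired non-responders and 4 responders, gave 989 calls, with Arglu1 at log2 -3.12 (adjusted p = 0.0174) and Rhox6 higher too (adjusted p = 0.000159). Batch O held no early responder. The largest clusters were 22 in responders (68.4%, cells mostly of replicate 2) and 25 in acquired non-responders (22.6%). Malat1 stood at 3477 ± 1085 CPM in acquired non-responders, far under its value in responders. Falling genes spanned a median of 58866 bp against 11379 bp for rising ones. Of the 675 falling genes, 560 reached 5 CPM in T cells of the same libraries, and 99.1% of those were lower there too, against 67.0% of all genes.

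**Figure D1:**
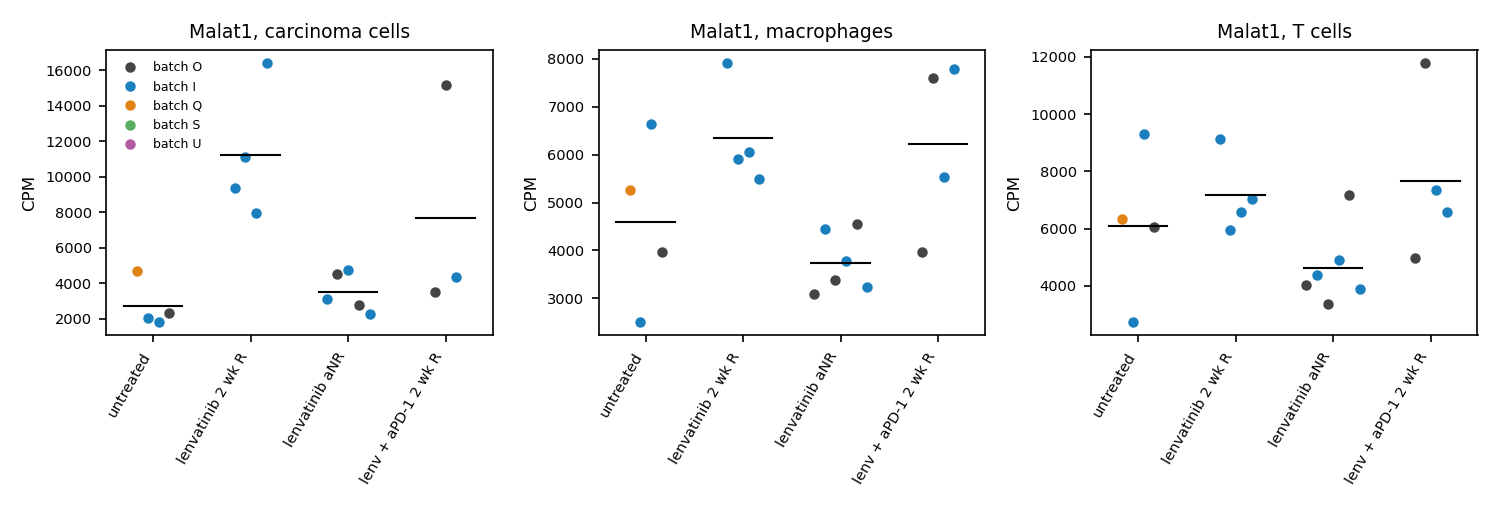
Malat1 (CPM of library sums, without normalization factors) in carcinoma cells, macrophages and T cells of untreated tumours, lenvatinib 2-week responders, lenvatinib acquired non-responders and lenvatinib plus anti-PD-1 2-week responders; points are libraries coloured by batch and lines are group means. Carcinoma cells of lenvatinib responders average 11219.7 CPM against 3477 CPM in acquired non-responders.

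Unfolded protein and integrated stress response genes were higher in carcinoma cells of acquired non-responders than of responders (14 of 15 members, median log2 0.59, adjusted p = 0.00143; adjusted p = 0.882 with an estimated correlation). The serine synthesis gene Psat1 rose from 5.90 ± 4.64 to 35.8 ± 57.7 CPM (3.05 ± 0.81, adjusted p = 0.0349). Without acquired non-responder replicate 4 the log2 difference was 1.08 and the adjusted p 0.354. Leaving out responder replicates 2 (0.0877), 3 (0.0813) and 4 (0.109) in turn also ended the call. Asns, which makes asparagine, stood at 91.8 ± 46.6 against 57.7 ± 7.14 CPM (adjusted p = 0.0743). Cell-cycle genes were higher (22 of 28, median 0.42, adjusted p = 0.00672; adjusted p = 0.924 with an estimated correlation). This ended without responder replicate 2 (0.0525) or 4 (0.0856). Among them, the replication licensing gene Mcm5 rose from 9.38 ± 5.27 to 19.9 ± 10.98 CPM (1.42 ± 0.35, adjusted p = 0.0238). That call was lost without acquired non-responder replicate 2 (0.0552) or 4 (0.0966) or responder replicate 2 (0.0697) or 4 (0.0935). In all 5 of 35 lists shifted, among them macrophage markers (14 of 15 higher, median 2.01, adjusted p = 0.00143; adjusted p = 0.924 with an estimated correlation), a sign of RNA from other cells that moves with the group. Adjusted over the list alone, 5 stress-response genes passed, against 1 over all genes.

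Against untreated tumours (n = 4), carcinoma cells of acquired non-responders (n = 5) carried more RNA of immune genes. T cell cytotoxicity genes were higher in 16 of 16 members (median log2 2.58, adjusted p = 1.49e-08; adjusted p = 0.132 with an estimated correlation). Among them is Nkg7, a granule protein gene of cytotoxic cells, at 7.40 ± 5.98 against 0.915 ± 0.637 CPM. T cell exhaustion genes (14 of 15, median 1.499, adjusted p = 3.92e-07) and regulatory T cell genes (10 of 11, median 1.28, adjusted p = 3.41e-05) were the only lists in any comparison that also passed with an estimated correlation (adjusted p = 0.0406 for each). Ctla4, a checkpoint receptor gene of T cells, stood at 1.84 ± 1.55 against 0.203 ± 0.14 CPM. These levels are far below those of T cells, and T cells made 18.6 ± 9.0% of the cells of acquired non-responders, so RNA of other cells lies within what was measured. Interferon gamma response genes were higher (21 of 22, median 1.16, adjusted p = 3.92e-07; adjusted p = 0.214 with an estimated correlation), as in the GTPase gene Gbp4 at 16.1 ± 21.1 against 2.36 ± 1.66 CPM. Hypoxia response genes were lower (25 of 33, median -0.28, adjusted p = 0.000141; adjusted p = 0.139 with an estimated correlation). Vegfa stood at 135 ± 52.1 against 197 ± 115 CPM and Car9 at 163 ± 61.6 against 223 ± 106 CPM. All these lists held without any 1 library, and 22 of 35 lists shifted. Of single genes, edgeR called 0, with 986 at an unadjusted p under 0.05 and 8 called by DESeq2. The smallest p belonged to the ubiquitin-conjugating enzyme gene Ube2e3 (chromosome 2, 78868124–78921293), at 56.9 ± 14.7 against 122 ± 20.6 CPM (-1.21 ± 0.25, adjusted p = 0.482), lower in 5 of 5. Its log2 difference was -1.41 within batch I and -0.82 within batch O, and each of those batches also gave 0 calls. The largest clusters were 25 in acquired non-responders and 10 in untreated tumours.

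Macrophages of lenvatinib responders (n = 4) differed from those of untreated tumours (n = 4) in hypoxia-inducible genes. Vegfa (chromosome 17, 46016993–46032369), the main growth factor for vessels, rose from 43.3 ± 10.1 to 299.9 ± 117 CPM (log2 2.96 ± 0.55, adjusted p = 0.0348), higher in 4 of 4. Egln1 (chromosome 8, 124908587–124949324), the oxygen-sensing prolyl hydroxylase that HIF itself induces, rose from 26.3 ± 17.6 to 125 ± 67.4 CPM (2.40 ± 0.51, adjusted p = 0.0476). The mitochondrial iron importer gene Slc25a37 rose from 10.5 ± 5.73 to 34.2 ± 8.25 CPM (1.83 ± 0.33, adjusted p = 0.0348). The actin regulators Coro1a (1294 ± 148 to 732 ± 59.5 CPM, -0.91 ± 0.18) and Cnn2 (197 ± 37.0 to 101 ± 8.43 CPM, -1.08 ± 0.20) fell (adjusted p = 0.0348 for both), lower in 4 of 4. In all, 21 genes rose and 8 fell of 14049. Of the 33 hypoxia response genes 28 were higher (median 1.05, adjusted p = 3.9e-08; adjusted p = 0.741 with an estimated correlation), with the lipid droplet gene Hilpda at 249 ± 65.7 against 39.9 ± 22.3 CPM. Glycolysis genes followed (16 of 17, median 0.98, adjusted p = 1.99e-07; adjusted p = 0.741 with an estimated correlation), as in Pgk1 at 735 ± 403 against 268 ± 72.9 CPM. Suppressive macrophage genes were higher as well (14 of 16, median 1.39, adjusted p = 3.67e-06; adjusted p = 0.266 with an estimated correlation). The arginine-degrading enzyme gene Arg1 stood at 518 ± 288 against 22.8 ± 18.8 CPM (4.50 ± 1.73, adjusted p = 0.222) and the checkpoint ligand gene Cd274 at 111 ± 42.2 against 37.2 ± 18.8 CPM (adjusted p = 0.0944), each higher in 4 of 4. Adjusted over the list alone, 12 hypoxia genes were higher and 1 lower, 9 glycolysis and 8 suppressive genes were higher, against 2, 0 and 1 over all genes.

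**Figure D2:**
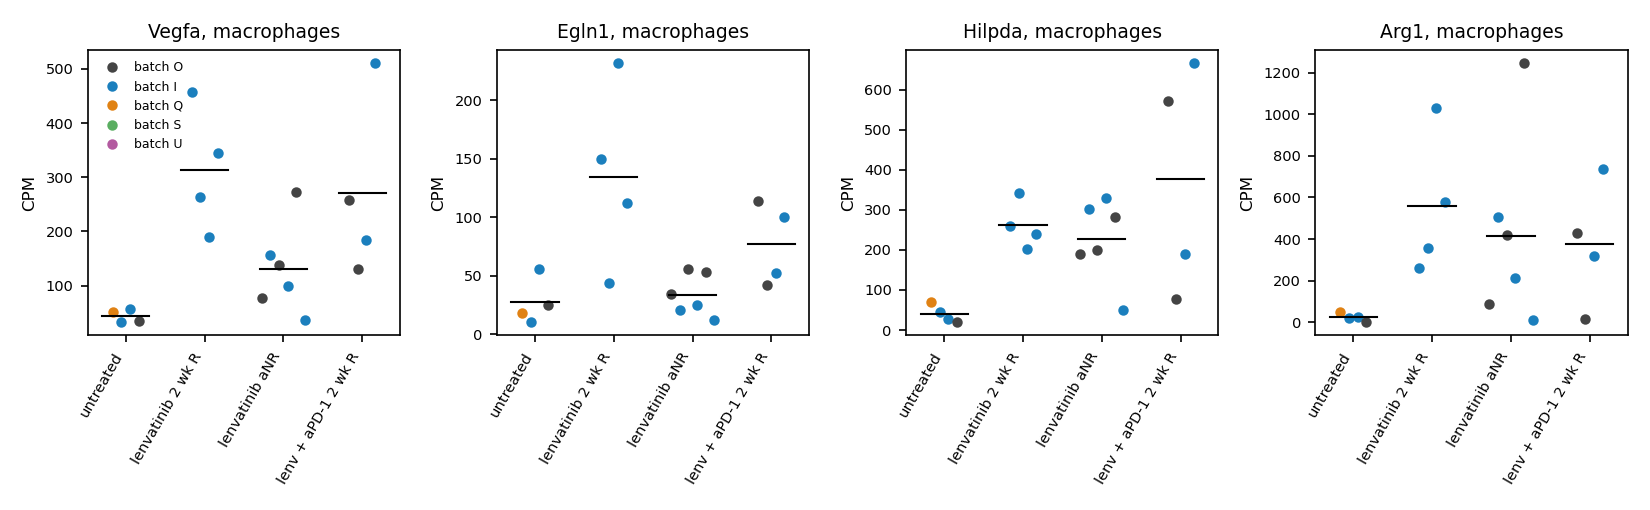
Vegfa, Egln1, Hilpda and Arg1 in macrophages (CPM of library sums, without normalization factors) in untreated tumours, lenvatinib 2-week responders, lenvatinib acquired non-responders and lenvatinib plus anti-PD-1 2-week responders; points are libraries coloured by batch and lines are group means. Vegfa of the lenvatinib responders lies above that of every untreated tumour.

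These 3 lists held without any 1 library, but the calls of single genes in macrophages of responders rest on few samples. The count of 29 was 0 without untreated replicate 2, untreated replicate 4, responder replicate 1 or responder replicate 4, 9 without responder replicate 3 and 740 without untreated replicate 3. DESeq2 called 709. Vegfa had an adjusted p of 0.15 without untreated replicate 2, 0.103 without untreated replicate 4, 0.0603 without responder replicate 1 and 0.103 without responder replicate 4. Egln1 lost its call without those 4 (0.171, 0.145, 0.0804 and 0.103), untreated replicate 1 (0.0697) or responder replicate 3 (0.0774). The other named genes lost theirs without the same 4 libraries at adjusted p from 0.0603 to 0.16. Within batch I, with 4 responders and 2 untreated tumours, Vegfa differed by log2 2.77 (adjusted p = 0.429) and 0 genes passed. The largest clusters were 12 in responders (28.6%) and 1 in untreated tumours (27.9%). Of the 21 risen genes, 17 reached 5 CPM in carcinoma cells, and 88.2% of those were higher there too, against 58.1% of all genes. Of those measured, 93.8% were higher in neutrophils (43.5% of all genes), 94.4% in dendritic cells (62.9%), 80% in T cells (66.4%) and 80% in NK cells (64.8%). Malat1 stood at 6345 ± 1072 against 4591 ± 1766 CPM in the macrophages, so a property that all classes of a library share, such as RNA quality, stays open for these genes.

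In macrophages of acquired non-responders (n = 6) against responders (n = 4), 141 genes rose and 355 fell of 14049. Egln1 fell from 125 ± 67.4 to 34.7 ± 18.2 CPM (-2.20 ± 0.46, adjusted p = 0.0172). Agap1, a regulator of endosomal traffic (chromosome 1, 89454806–89897617), fell from 55.3 ± 18.9 to 11.7 ± 5.09 CPM (-2.33 ± 0.42, adjusted p = 0.00949), lower in 6 of 6. The growth factor gene Igf1 fell from 82.7 ± 50.4 to 18.0 ± 15.9 CPM (-2.14 ± 0.55, adjusted p = 0.0359). Type I interferon genes were higher (20 of 20, median 0.84, adjusted p = 9.83e-07; adjusted p = 0.704 with an estimated correlation), led by Ifi27l2a at 1891 ± 1161 against 601 ± 402 CPM (adjusted p = 0.0515). MHC class I presentation genes were higher (15 of 16, median 0.56, adjusted p = 1.15e-05; adjusted p = 0.704 with an estimated correlation). The immunoproteasome genes Psme1 (243 ± 52.8 to 426 ± 75.9 CPM, 0.85 ± 0.18, adjusted p = 0.018), Psmb8 (338 ± 82.8 to 580.1 ± 104 CPM, adjusted p = 0.0225) and Psmb10 (121 ± 16.8 to 201 ± 32.6 CPM, adjusted p = 0.0274) rose. Oxidative phosphorylation genes were higher (20 of 20, median 0.33, adjusted p = 4.34e-05; 0.704 with an estimated correlation), and these 3 lists held without any 1 library. Arg1 stayed at 421 ± 438 against 518 ± 288 CPM (log2 -0.34 ± 1.27, adjusted p = 0.942), with a positive sign without acquired non-responder replicate 6 (0.20) or responder replicate 3 (0.12).

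Of these macrophage genes, Agap1 lost its call only without responder replicate 4 (adjusted p = 0.0541). Egln1 lost it without acquired non-responder replicate 2 (0.0558) or 4 (0.0565) or responder replicate 4 (0.0541). Psme1 lost it without acquired non-responder replicate 4 (0.0661) or responder replicate 4 (0.0628), and Psmb8 without acquired non-responder replicate 2 (0.0558) or 4 (0.0776) or responder replicate 4 (0.0773). Psmb10 lost it without acquired non-responder replicate 2 (0.0558), 4 (0.0891) or 6 (0.0536) or responder replicate 3 (0.0528) or 4 (0.0829). Igf1 lost it without acquired non-responder replicate 2 (0.0772), 3 (0.0512) or 4 (0.102) or responder replicate 3 (0.119) or 4 (0.0773). The total of 496 was 74 without acquired non-responder replicate 2, 34 without 4, 770 without 5, 130 without 6, 310 without responder replicate 2 and 24 without responder replicate 4. DESeq2 called 1378. Batch I alone (3 against 4) gave 126 calls, with Agap1 at log2 -2.51 (adjusted p = 0.0264). Malat1 was lower here without passing (adjusted p = 0.147), at 6345 CPM in macrophages of responders and 3749 CPM in those of acquired non-responders, and 98.9% of 276 falling genes were also lower in T cells, against 67.0% of all genes. The largest clusters were 12 in responders and 1 in acquired non-responders (24.2%).

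Lenvatinib acts on the endothelium, and responder tumours held 0.383 ± 0.078% endothelial cells against 1.42 ± 0.56% in untreated tumours, lower in 4 of 4 (exact permutation p = 0.0286, the smallest that 4 against 4 can give; adjusted p = 0.514). Within the batch that holds both groups the difference was -1.07 percentage points. Acquired non-responders held 0.315 ± 0.27%, close to responders (exact p = 0.643, adjusted p = 0.949; +0.0971 points within the shared batch) and lower than every untreated tumour in 6 of 6 (exact p = 0.00476, adjusted p = 0.457). Only responder replicate 2 had enough endothelial cells for gene tests (20 cells, 42613 UMIs), and this lone library is assumed to vary like the other groups. There, Kcne3, a potassium channel subunit gene of sprouting tip cells (chromosome 7, 100176502–100184869), fell from 1038 ± 273 CPM (n = 4) to 40.2 CPM (2 counts, n = 1; adjusted p = 0.004), 21.4-fold by pooled counts with a counting interval of 5.92 to 177. This call held without any 1 untreated library, but the lone responder library could not be left out. With at least 10 cells per library, chosen after the data were seen, 3 responder libraries entered and Kcne3 differed by -4.02 (adjusted p = 3.24e-06). Sparc, a matrix protein gene, stood at 4179.9 CPM in the lone library against 17147 ± 5181 CPM (adjusted p = 0.03), and passed with 3 responder libraries too (adjusted p = 0.00546). The tip-cell peptide hormone gene Apln (X, 48025146–48034853; 0 against 823 ± 193 CPM) and the capillary lipase anchor gene Gpihbp1 (2653 against 11795 ± 4084 CPM) passed only with the lone library (adjusted p = 0.0488 for both). With 3 responder libraries they did not: Gpihbp1 differed by -1.69 ± 0.41 (adjusted p = 0.098) after -2.22 ± 0.42. Apln differed by -2.65 ± 0.65 (adjusted p = 0.138), where the lone library alone gave at least 11.7-fold less with a floor of 3 counts (70.4 CPM). Both differences shrank without turning, so whether they are lower stays open.

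All 22 tested tip cell and sprouting genes were lower in these endothelial cells (median log2 -1.34, adjusted p = 3.07e-10; adjusted p = 0.163 with an estimated correlation; fry p = 0.0483), and stayed so without any 1 untreated library. These genes share the deviation of 1 library, which could not be left out. With 3 responder libraries of at least 10 cells the list had an adjusted p of 2.16e-12. Of the 22 genes 7 passed adjusted over the list alone against 2 over all genes. The lenvatinib targets Kdr and Flt1, receptors for VEGF, stood at 603 against 1065 ± 229.7 CPM and at 422 against 929 ± 287 CPM (adjusted p = 0.639 for both). Dissociation stress genes were higher in the same cells (14 of 15, median 0.91, adjusted p = 0.000107; 0.682 with an estimated correlation), with Egr1 at 1768 against 537 ± 97.5 CPM. The 2 genes that rose were the antibody light chain genes Igkv1-117 and Igkv1-135, which mark RNA of plasma cells; both were chosen after their values were seen. In all 6 genes passed, against 16 without untreated replicate 3 and 18 within batch I (1 against 2). Apln lost its call without untreated replicate 2 (adjusted p = 0.113) or 3 (0.063), Gpihbp1 without untreated replicate 1 (0.0718) or 4 (0.0663), and Sparc without untreated replicate 1 (0.0614). Acquired non-responders (n = 3) against that library gave 1 call, Igkv1-117 at 11.4 ± 12.8 against 1226 CPM (adjusted p = 0.0307). It ended without acquired non-responder replicate 2 (0.147) or 6 (0.427), and with at least 10 cells per library 0 genes passed, so it reflects that 1 library. Kcne3 stood at 147 ± 74.4 against 40.2 CPM (adjusted p = 0.738), a ratio of 2.96 with a counting interval of 0.777 to 25.1.

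T cells made 16.5 ± 6.5% of lenvatinib responder tumours against 5.68 ± 3.19% of untreated ones, higher in 3 of 4 (exact p = 0.0857, adjusted p = 0.588; +8.14 points within the shared batch). Macrophages made 17.0 ± 5.2% against 27.9 ± 14.9% (exact p = 0.286, adjusted p = 0.72; -12.6 points within the shared batch). In acquired non-responders T cells made 18.6 ± 9.0% (higher than every untreated tumour in 5 of 6, exact p = 0.0333, adjusted p = 0.457). NK cells made 7.60 ± 5.72% against 1.36 ± 1.22% (5 of 6, exact p = 0.0381), and carcinoma cells 12.8 ± 14.9% against 38.3 ± 17.0% (lower in 5 of 6, exact p = 0.0429). Unnamed epithelial and mesenchymal cells (912 in replicate 3, 118 in replicate 1) were not counted as carcinoma. None of the 96 share tests passed after adjustment, and all are two-sided. Replicates are separate tumours, but the labels do not say whether they come from separate mice, so each p measures spread between these samples.

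**Figure D3:**
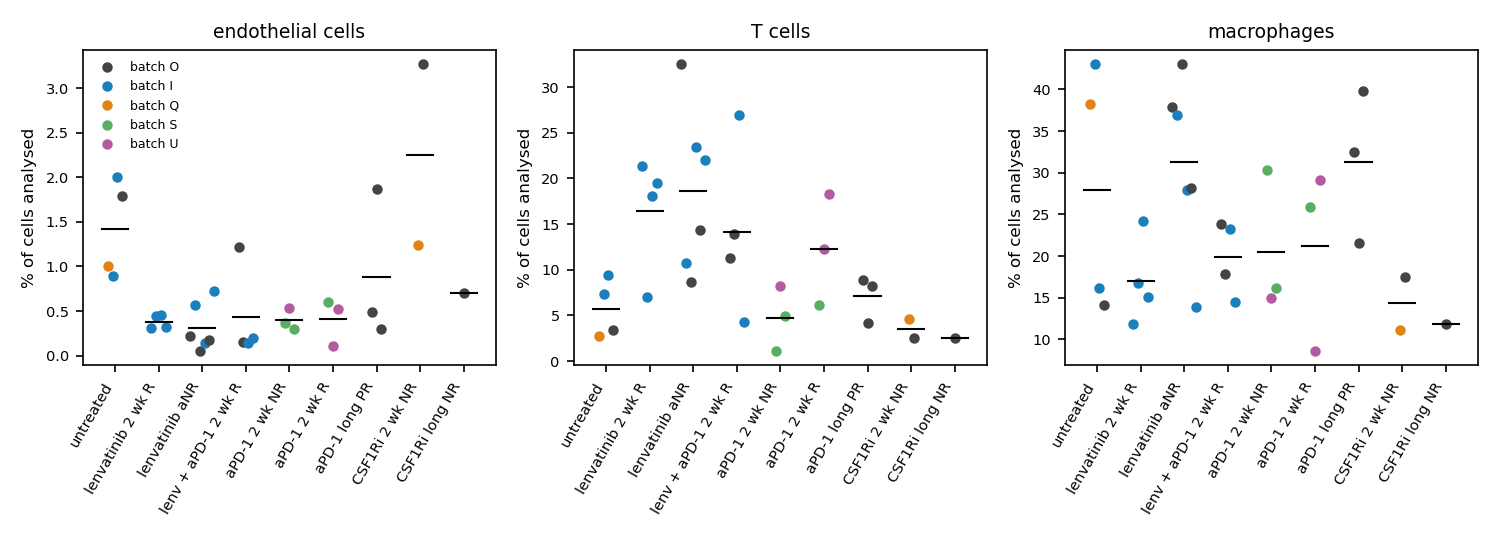
Percent of all analysed cells that are endothelial cells, T cells and macrophages in 9 groups of tumours; points are libraries coloured by batch and lines are group means. Endothelial cells make 1.42% of untreated tumours and 0.383% of lenvatinib 2-week responders on average.

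Adding anti-PD-1, an antibody that blocks the T cell checkpoint receptor PD-1, to lenvatinib was examined in 2-week responders (3 libraries with enough carcinoma cells). Against untreated tumours (n = 4), the epithelial adhesion gene Cdh1 (chromosome 8, 106603351–106670246) stood at 73.3 ± 42.9 against 23.2 ± 7.01 CPM (log2 1.97 ± 0.46, adjusted p = 0.608), higher in 3 of 3, and the heat shock gene Hspa1b at 147 ± 74.1 against 36.2 ± 21.4 CPM (2.70 ± 0.70, adjusted p = 0.626). edgeR called 0 genes, with 1173 at an unadjusted p under 0.05 and 43 called by DESeq2. Batch I (1 against 2) gave 1 and batch O (2 against 1) gave 0. The largest clusters were 47 with the combination (42.1%) and 10 in untreated tumours. Combination replicate 1 gave 2981 of the 3643 pooled combination cells. Of 35 lists 13 shifted. Complement-high macrophage genes were lower (13 of 14, median -1.89, adjusted p = 0.000104; adjusted p = 0.211 with an estimated correlation; held without any 1 library). By camera endothelial markers were lower too (9 of 13 members, median -2.51, adjusted p = 0.000133; 0.211 with an estimated correlation), both measures of RNA from other cells. Dissociation stress genes were higher (11 of 15, median 0.31, adjusted p = 0.00876; 0.488 with an estimated correlation), which ended without untreated replicate 1 (0.0595) or 3 (0.0811) or combination replicate 1 (0.164). Malat1 (7680 ± 6513 against 2691 ± 1330.0 CPM) and Neat1 (686 ± 605 against 154 ± 64.9 CPM) stood higher in the combination, so RNA quality or nuclear RNA stays open for these lists. Cell-cycle genes were lower (21 of 28, median -0.38, adjusted p = 0.014; adjusted p = 0.715 with an estimated correlation), as in Mki67 at 39.9 ± 20.8 against 78.1 ± 12.5 CPM. The list ended without untreated replicate 2 (0.0672) or 4 (0.728) or combination replicate 1 (0.171) or 2 (0.733). Hypoxia response genes were lower (24 of 33, median -0.15, adjusted p = 0.035; 0.488 with an estimated correlation), which ended without untreated replicate 3 (0.149) or 4 (0.0717) or combination replicate 2 (0.0979) or 3 (0.968).

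Against lenvatinib alone (n = 4), no gene passed in carcinoma cells of combination responders (n = 3). The cytokine gene Tgfb1 (chromosome 7, 25687002–25705077) stood at 5.40 ± 1.41 against 41.5 ± 11.9 CPM (log2 -2.86 ± 0.50, adjusted p = 0.153), lower in 3 of 3. Cox4i2, a cytochrome oxidase subunit gene that hypoxia induces, stood at 72.7 ± 82.7 against 0.247 ± 0.494 CPM (1 count; adjusted p = 0.396), and the respiratory chain assembly gene Uqcc2 at 248 ± 44.5 against 105 ± 17.1 CPM (1.29 ± 0.30, adjusted p = 0.423). edgeR called 0 of 17048 genes, with 1595 at an unadjusted p under 0.05 and 91 called by DESeq2. Batch I (1 against 4) gave 2. The largest clusters were 47 with the combination (cells mostly of replicate 1) and 22 with lenvatinib alone (mostly of replicate 2). Inflammatory cytokine genes were lower (18 of 20, median -2.12, adjusted p = 2.37e-05; adjusted p = 0.435 with an estimated correlation), as in the prostaglandin synthase gene Ptgs2 at 0.652 ± 0.291 against 3.75 ± 2.28 CPM. Tip cell genes were lower (15 of 20, median -0.92, adjusted p = 0.00623; adjusted p = 0.0722 with an estimated correlation; fry p = 0.0115), as in the collagen gene Col4a1 at 244 ± 83.9 against 692 ± 394 CPM. Both held without any 1 library. Ptgs2 also leads a neutrophil cluster, and Malat1 averaged 7680 against 11219.7 CPM, so RNA of other cells or RNA quality stays open for both. Oxidative phosphorylation genes were higher (20 of 20, median 0.59, adjusted p = 0.00127; adjusted p = 0.787 with an estimated correlation), which ended without combination replicate 1 (0.635). In T cells (n = 4 against 4; 11779 genes) edgeR and DESeq2 called 0 genes, 414 had an unadjusted p under 0.05, and 0 of 29 lists shifted. Ifng, the interferon gamma gene, stood at 256 ± 143 against 116 ± 27.8 CPM (0.82 ± 0.57, adjusted p = 1). T cells made 14.1 ± 9.5% of combination responders, against 16.5 ± 6.5% with lenvatinib alone (exact p = 0.686, adjusted p = 0.949; -0.88 points within shared batches; +0.899 without combination replicate 4). In untreated tumours they made 5.68 ± 3.19% (exact p = 0.114, adjusted p = 0.61; +7.42 points within shared batches).

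Response and non-response to anti-PD-1 at 2 weeks (n = 3 each) were compared within batches S and U. In T cells, cell-cycle genes were lower in responders in 28 of 28 members (median log2 -0.91, adjusted p = 4.37e-16; adjusted p = 0.505 with an estimated correlation). Cdk1 stood at 40.02 ± 2.89 against 93.1 ± 13.04 CPM, lower in 3 of 3. Naive and memory T cell genes were higher (11 of 11, median 1.10, adjusted p = 2.97e-08; adjusted p = 0.505 with an estimated correlation). Tcf7, a transcription factor gene of stem-like and naive T cells (chromosome 11, 52252371–52283014), stood at 117 ± 31.3 against 52.1 ± 6.90 CPM (1.08 ± 0.34), higher in 3 of 3. Interferon gamma response genes were higher (18 of 20, median 0.79, adjusted p = 1.78e-08; 0.505 with an estimated correlation), as in Irf1 at 243 ± 9.29 against 118 ± 14.8 CPM, and these 3 lists held without any 1 library. Type I interferon genes were higher (20 of 20, median 1.21, adjusted p = 8.47e-09; 0.505 with an estimated correlation), which ended without non-responder replicate 2 (0.082). Of 11779 single genes edgeR called 0, 302 had an unadjusted p under 0.05 and DESeq2 called 4. Batches S (1 responder against 2 non-responders) and U (2 against 1) each left an arm of 1 library and support no gene. Malat1 stood at 5149 ± 1031 CPM in T cells of responders against 3872 ± 525.9 CPM, so RNA quality stays open. T cells made 12.3 ± 6.0% against 4.75 ± 3.5% of cells, higher in 2 of 3 (exact p = 0.2, where the smallest possible is 0.1; adjusted p = 0.679).

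In macrophages of the same anti-PD-1 tumours, type I interferon genes (20 of 20, median log2 1.44, adjusted p = 1.31e-12) and interferon gamma response genes (22 of 22, median 1.05, adjusted p = 1.09e-10) were higher in responders, each at 0.654 with an estimated correlation. Cell-cycle genes were lower (26 of 28, median -1.11, adjusted p = 7.11e-10; 0.654 with an estimated correlation). All 3 held without any 1 library. In the same macrophages Neat1 stood at 341 ± 59.98 against 213 ± 30.3 CPM and Malat1 at 4471 ± 218 against 3530 ± 440 CPM, and dissociation stress genes were higher (14 of 15, median 0.33, adjusted p = 0.0431; 0.783 with an estimated correlation; turned without non-responder replicate 2), so RNA quality or handling stays open as a source. The interferon-induced sensor gene Zbp1 stood at 104 ± 51.6 against 56.2 ± 31.2 CPM, and Ly6c2, a marker gene of inflammatory monocytes, at 215 ± 95.1 against 49.3 ± 56.8 CPM, higher in 3 of 3. The monocyte list was higher in 12 of 12 (median 1.35, adjusted p = 3.21e-05; 0.654 with an estimated correlation) but not without non-responder replicate 2 (0.245). Prg4 (chromosome 1, 150449412–150466165), Selp and Padi4 were the 3 calls of 14049 genes (adjusted p = 8.73e-06, 0.0162 and 0.0162), all chosen after their values were seen. Responder replicate 1 carried them, with 93.8, 34.0 and 31.4 CPM. Without it their adjusted p was 0.844, 0.837 and 0.837, and 0 genes passed. Selp and Padi4 also lost their calls without non-responder replicate 1 (0.561 and 0.152; 1 call left) or 3 (0.48 and 0.48; 1 call left). Without non-responder replicate 2 there were 9. Prg4 encodes lubricin, and the complement gene C4b stood at 298 CPM in responder replicate 1. The largest clusters were 4 in responders (25.1%), led by monocyte genes such as Ear2, and 1 in non-responders (21.4%), led by genes such as C1qa. A change in the mix of monocytes and macrophages was not tested and stays open. Macrophages made 21.2 ± 11.05% against 20.5 ± 8.5% of cells (exact p = 1). The sign of the difference turned without responder replicate 1 (-1.56 points) or 3 (-3.19) or non-responder replicate 2 (-1.98) or 3 (-1.39).

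Carcinoma cells of anti-PD-1 responders (n = 3) against non-responders (n = 3) gave no gene past the threshold. Plk2, a stress-induced kinase gene, stood at 6.79 ± 6.74 against 61.1 ± 25.3 CPM (log2 -3.53 ± 0.81, adjusted p = 0.455). Amotl2, a target gene of YAP signalling, stood at 27.4 ± 9.88 against 72.3 ± 23.4 CPM (-1.32 ± 0.31, adjusted p = 0.458), both lower in 3 of 3. Rhox6 stood at 102 ± 117 against 0.265 ± 0.252 CPM (9.02 ± 2.13, adjusted p = 0.458), higher in 2 of 3. edgeR called 0 genes, with 1146 at an unadjusted p under 0.05 and 94 called by DESeq2. Batches S (1 responder against 2 non-responders) and U (2 against 1) each left an arm of 1 library and support no gene. Malat1 stood at 1596 ± 1061 against 4286 ± 2891 CPM, and dissociation stress genes were lower (9 of 15, adjusted p = 0.0424; 0.903 with an estimated correlation; turned without non-responder replicate 2). Responder replicates 2 and 3 had 33 and 59 carcinoma cells. The largest clusters were 17 in responders (52.8%) and 22 in non-responders (30.7%). Of 4334 pooled responder cells 4242 came from replicate 1. MHC class II genes were higher (9 of 10, median 2.05, adjusted p = 0.000393; adjusted p = 0.903 with an estimated correlation), with the invariant chain gene Cd74 at 1624 ± 1102 against 256 ± 211 CPM. This ended without non-responder replicate 2 (0.335), and RNA of other cells stays open. Inflammatory cytokine genes were lower (16 of 20, median -0.83, adjusted p = 0.000393; adjusted p = 0.903 with an estimated correlation), without any 1 library too, as in the neutrophil chemokine gene Cxcl1 at 786 ± 225 against 1714 ± 901 CPM, lower in 3 of 3. Hypoxia response genes were lower (27 of 33, median -0.32, adjusted p = 0.0194; 0.903 with an estimated correlation), with the glucose transporter gene Slc2a1 at 142 ± 42.1 against 276 ± 72.2 CPM. This ended without non-responder replicate 2 (0.246) or responder replicate 1 (0.0509) or 2 (0.209).

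After long anti-PD-1 treatment, carcinoma cells of partial responders (n = 3) were compared with untreated ones (n = 4). Hypoxia response genes were lower (28 of 33, median log2 -0.41, adjusted p = 5.54e-06; adjusted p = 0.171 with an estimated correlation). The mitophagy gene Bnip3 stood at 750.4 ± 143 against 1244 ± 463 CPM and the prolyl hydroxylase gene Egln3 at 315 ± 45.7 against 504 ± 197 CPM. Glycolysis genes were lower (15 of 17, median -0.42, adjusted p = 0.00126; adjusted p = 0.171 with an estimated correlation), as in Hk2, the hexokinase gene, at 41.9 ± 4.16 against 79.1 ± 23.4 CPM, lower in 3 of 3. Both held without any 1 library, and 11 of 35 lists shifted. The coagulation factor gene F10 had the smallest p of a rising gene (42.4 ± 66.8 against 5.50 ± 9.10 CPM, adjusted p = 0.948). edgeR called 0 of 17048 genes, with 453 at an unadjusted p under 0.05 and 6 called by DESeq2. Leaving out untreated replicate 1 or 2 gave 1 call, and batch O (3 against 1) gave 0, with Bnip3 at log2 -1.09 and Hk2 at -0.13. T cells made 7.12 ± 2.5% of partial responders against 5.68 ± 3.19% (exact p = 0.543, adjusted p = 0.883; +3.77 points within the shared batch).

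CSF1R inhibition, which blocks a survival signal of macrophages, was compared with no treatment in 3 tumours (2 at 2 weeks and 1 at long term, all non-responders) against 4. Cell-cycle genes were lower in macrophages in 28 of 28 members (median log2 -1.67, adjusted p = 5.4e-21; adjusted p = 0.683 with an estimated correlation), and stayed so without any 1 library. Of them 13 passed adjusted over the list alone against 0 over all genes. The G1 cyclin gene Ccnd1 (chromosome 7, 144929931–144939925) stood at 8.39 ± 9.14 against 71.4 ± 39.3 CPM (-3.89 ± 0.74, adjusted p = 0.169). The replication licensing gene Mcm2 stood at 5.70 ± 1.11 against 18.9 ± 7.49 CPM (-2.15 ± 0.40, adjusted p = 0.169), both lower in 3 of 3. Cx3cr1, the fractalkine receptor gene of resident macrophages, stood at 158 ± 101 against 309.8 ± 62.6 CPM (adjusted p = 0.191), and Arg2 at 46.9 ± 36.7 against 8.55 ± 3.06 CPM (2.42 ± 0.48, adjusted p = 0.169). Suppressive macrophage genes were higher (12 of 16, median 0.47, adjusted p = 0.00332; 0.683 with an estimated correlation), which ended without the long-term tumour (0.0922) or 2-week replicate 2 (0.0789). Hypoxia response genes were higher (24 of 33, median 0.27, adjusted p = 0.00519; 0.977 with an estimated correlation), which ended without untreated replicate 3 (0.075) or the long-term tumour (0.991). edgeR called 0 of 14049 genes, with 940 at an unadjusted p under 0.05 and 89 called by DESeq2. Leaving out untreated replicate 4 gave 1, and batch O (2 against 1) gave 0, with Ccnd1 at log2 -2.71. Macrophages made 13.5 ± 3.5% of these tumours against 27.9 ± 14.9% (exact p = 0.229, adjusted p = 0.679; -12.7 points within shared batches). The largest macrophage clusters were 4 at 2 weeks (30.1%), 26 at long term (62.9%) and 1 in untreated tumours (27.9%). Cluster 4 is led by monocyte genes, so a change of mix stays open here too.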

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

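The tests in this part were chosen after the results were seen, except the batch test of the falling carcinoma genes and the counts of other splits for macrophages.

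The 675 genes that fell in carcinoma cells of lenvatinib acquired non-responders against 2-week responders are long and move together with the nuclear RNA Malat1. Sequencing batch was checked within batch I alone. The median log2 difference of the 675 genes there was -1.66, against -1.29 over all batches for the 641 that reached 5 CPM. This rereading cannot decide, because the genes were called in a fit with a batch term. In that comparison all 4 responders and 3 of the 5 acquired non-responders lie in batch I. A separate fit of batch I alone also called genes, so a difference exists between libraries of 1 batch. A property that all classes of a library share, such as RNA quality or a larger nuclear fraction, is a candidate explanation. Of those measured in T cells 99.1% were lower there too, at a median of -0.92, where 67.0% of all genes were lower. A response to treatment in every class gives the same picture and stays open, because every responder library shares the treatment.

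Y-linked transcripts were nearly absent from carcinoma cells in 13 of 34 libraries, at no more than 7.84% of the macrophage level of the same library, against 21.5 to 163% in the other 21. The tables argue against a mislabelled library from a female mouse, since macrophages of those 13 libraries held at least 83.5 CPM of Y-linked genes (median over libraries 121 CPM), and against too few counts, since the upper counting limit of the carcinoma value stayed under 10% of the macrophage value in 12 of the 13. Loss of the Y chromosome from carcinoma cells, known in kidney cancer, may explain the pattern. X-linked partner genes, which should stay, kept at least 50% of the macrophage level in 12 of the 13. They kept only 42.5% in anti-PD-1 2-week responder replicate 2, with 33 carcinoma cells, so the test left it undecided. Responder replicate 3, with 59 carcinoma cells, kept Y transcripts at 56.1% and the partners at 41.8%. A low partner level thus also occurred where Y transcripts were kept. Female carcinoma cells in a library of a male mouse stay open too: Xist was at least 10 CPM in carcinoma cells of 6 of the 13, up to 217 CPM in untreated replicate 2 (3.18 CPM in its macrophages), but under it in the other 7, and up to 30.3 CPM where Y transcripts were kept. No relation to treatment was tested.

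In acquired non-responder replicate 3, an unnamed cluster of 912 cells with epithelial and mesenchymal genes carried a block of chromosome 9 far above its level elsewhere. Over 9 genes from 6928503 to 8042823 the median was 5.81 log2 units above the median over tumours, where the highest window of untreated carcinoma cells was 1.73. A gain of DNA copies may explain it, since the window exceeded every window on other chromosomes in those cells by 3.10 log2 units, with the next at 2.71 on chromosome 11. The tables argue against RNA of a cell type found among the clusters, since a mixture cannot exceed its source: in each of the 9 genes, among them Yap1, Birc2, Birc3, Mmp7 and Mmp10, the highest of the 80 other clusters with at least 20 cells stayed at 57.4% or less of the level of these cells. RNA of a cell type absent from the clusters stays open: 16 genes on other chromosomes, such as Col1a1 and Postn, were raised at least as much as the median of the window. They were also raised in the same cluster of replicate 1 and so may belong to its cells. Over 21 genes in and around the block the median was 3.05 log2 units, and 0.498 in that cluster of replicate 1 (118 cells). No DNA was measured.

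Between classes under the same contrast, the hypoxia response score of macrophages minus that of carcinoma cells was higher in lenvatinib responders than in untreated tumours by 1.01 log2 units (exact p = 0.0286, the smallest possible, 4 of 4) and in acquired non-responders by 0.738 (exact p = 0.0317, 4 of 5). For glycolysis the differences were 1.19 (exact p = 0.0286, 4 of 4) and 1.08 (exact p = 0.0317, 4 of 5). Adjusted over all 10 such tests, none passed (adjusted p = 0.0794 for these 4). Combination responders against untreated tumours differed by 0.855 for hypoxia (exact p = 0.143, 2 of 3) and 0.846 for glycolysis (exact p = 0.0857, 2 of 3), and the other 4 tests by -0.273 to -0.112 (exact p of at least 0.317).

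A single library lay far from the rest of its group in 15 of 223 groups tested, close to the 11.2 (1 in 20) that chance gives. In carcinoma cells these were Runx1 in lenvatinib responder replicate 3 (14.7 CPM), Car9 (66.5 CPM) and Pfkl (187 CPM) in untreated replicate 1. They were also Rhox6 in responder replicate 3 (0.543 CPM), Snhg11 (3.95 CPM), Psat1 (12.8 CPM) and Cox4i2 (0.988 CPM) in responder replicate 1, and Cxcl5 in responder replicate 4 (32.2 CPM). The values of Rhox6 and Cox4i2 are each 1 count against 0 in the other 3 libraries, so they show no deviation. In macrophages they were Cnn2 in responder replicate 2 (88.0 CPM), Slc35c2 in untreated replicate 2 (100.1 CPM), Spp1 in responder replicate 1 (1916 CPM), Igf1 in responder replicate 3 (158 CPM) and Ifitm3 in acquired non-responder replicate 4 (5150.3 CPM). The others were Tmem259 in T cells of responder replicate 2 (17.7 CPM) and endothelial cells in combination responder replicate 1 (1.22% of cells). Outside the comparisons, the digestive enzyme gene Ctrb1 stood at 2114 CPM in the long-term tumour under CSF1R inhibitor plus anti-PD-1, against at most 0.023 CPM in untreated tumours and normal kidneys.

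Other splits of the same samples tested how many calls chance gives. For acquired non-responders against responders, only the real grouping among 60 splits reached its own count. This held in carcinoma cells (867 genes with the trend held fixed, highest other 682) and in macrophages (496 genes, highest other 177). Chance is unlikely there but not excluded, since normalization and the genes tested were also those of the real grouping. Other splits gave as many calls as the 29 genes of macrophages in responders against untreated tumours (3 of 35 splits, highest other 58). They also did for the 1 gene that carcinoma cells of partial responders gave with the trend held fixed (5 of 35, highest other 1). Chance stays open for both. With 0 real calls every split gives as many. This was 35 of 35 for carcinoma cells of lenvatinib responders (highest other 1) and of combination responders against untreated tumours (1) and lenvatinib (6). The same held for macrophages under CSF1R inhibition (84) and T cells of combination against lenvatinib responders (13). It was 60 of 60 for carcinoma cells of acquired non-responders against untreated tumours (highest other 282). Splits with 282 and 84 genes where the real one gave 0, the highest of 60 and 35, point to a structure of the samples, which was not tested. For anti-PD-1 responders against non-responders the 10 splits are too few for a share under 0.05. Carcinoma and T cells each gave 0 genes (highest other 0, 10 splits as many) and macrophages 3 (highest other 4, 2 splits as many).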

How the results depend on the processing

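Some alternatives were added after the data were seen, as listed above. Of 2175 values of named genes under these and the other alternatives apart from leaving out 1 library, 1924 kept their direction and side of the threshold, 84 passed it newly, 167 no longer passed and 0 turned. Of 546 values of lists 412 stayed, 128 no longer passed and 6 turned. With 1 library left out, of 1324 values of genes 1130 stayed, 15 passed newly, 176 no longer passed and 3 turned, and of 640 values of lists 532 stayed, 103 no longer passed and 5 turned. Depth limits endothelial cells (1 responder library of 20 cells) and carcinoma cells of responders with few cells. Causes not named were not tested.

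By DESeq2, carcinoma cells gave 1182 genes for lenvatinib responders against untreated tumours (0 by edgeR), 2149 for acquired non-responders against responders (866), 8 for acquired non-responders against untreated (0), 43 and 91 for the combination against untreated tumours and against lenvatinib (0 and 0). They gave 94 for anti-PD-1 responders (0) and 6 for partial responders (0). Macrophages gave 709 (29), 1378 (496), 15 (3) and 89 (0) for lenvatinib responders, acquired non-responders, anti-PD-1 responders and CSF1R inhibition, endothelial cells 14 (6) and 2 (1), and T cells of anti-PD-1 responders 4 (0). Counts by edgeR are the ones to set the next values against. With only the compared groups in the fit, carcinoma cells gave 4 for lenvatinib responders, 1411 for acquired non-responders against responders and 2 for anti-PD-1 responders, macrophages 0, 1044 and 0. Endothelial cells gave 31 and 47. With a replicate block, although replicate numbers did not pair samples, carcinoma cells gave 5, 0 and 23, macrophages 1, 0 and 0, and T cells of the combination against lenvatinib 1 (0 without it). Within batch I, carcinoma cells gave 10 for lenvatinib responders and 1 and 2 for the combination. Macrophages gave 0 for lenvatinib responders and 126 for acquired non-responders, and endothelial cells 18 and 2, with fewer samples (the combination and endothelial responders with 1 library). Within batch S (1 responder against 2 non-responders) anti-PD-1 gave 3 in carcinoma cells, 8 in macrophages and 72 in T cells (0), and within batch U (2 against 1) 99, 0 and 9; with an arm of 1 library these support no gene.

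Without a batch term, acquired non-responders against responders gave 370 in carcinoma cells and 0 in endothelial cells, the combination against lenvatinib 1. Macrophages gave 68 for lenvatinib responders and 0 for anti-PD-1 responders. Without a low-count filter, with more genes tested, carcinoma cells gave 1 for the combination against lenvatinib and 1 for partial responders, macrophages 10 and 276, and endothelial cells 43 and 13. With doublets kept, partial responders gave 1, macrophages of lenvatinib responders 46, and endothelial cells 1 and 0. At the higher Leiden resolution macrophages gave 2 for lenvatinib responders and 3 for CSF1R inhibition, and 86.2% of cells were named (91.4%). Without the libraries in doubt, macrophages of anti-PD-1 responders gave 1 and endothelial cells 2 and 0. With at least 10 cells endothelial cells gave 18 and 0. With at least 50 cells carcinoma cells of lenvatinib responders gave 1. Camera with an estimated correlation left 2 of 124 list calls.

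Some directions turned. Of these, only MHC class II genes in carcinoma cells of partial responders passed the threshold in both directions. The share of endothelial cells in acquired non-responders against responders was +0.0971 points in shared batches (-0.0679 over all). T cells of the combination against lenvatinib stood at +0.0653 (log2) by the edgeR test of cell counts (-2.39 points in the exact test). Macrophages of anti-PD-1 responders (0.779 points of all cells) stood at -0.421 points outside carcinoma and -4.19 of named cells. Lists that turned in carcinoma cells with a replicate block had adjusted p values of, for cell cycle, 0.881 and matrix 0.176 in the combination against lenvatinib, and in partial responders tip cell genes 0.992, unfolded protein response 0.992 and MHC class II 0.00609 (0.864 without a batch term). With 1 library left out these were, for cell cycle in the combination against lenvatinib, 0.0536 (combination replicate 3; otherwise 0.000126 to 0.292), and in anti-PD-1 carcinoma cells 0.804 (non-responder replicate 2) and 0.951 (responder replicate 2; lowest 1.31e-05), dissociation stress there 0.559 (lowest 2.01e-05) and in macrophages 0.512 (lowest 0.00125), without non-responder replicate 2 for both. Of genes, the log2 difference of Spp1 in macrophages of lenvatinib responders was -0.041 without untreated replicate 3 (highest 1.70 without 2), and that of Arg1 in macrophages of acquired non-responders 0.20 without replicate 6 and 0.12 without responder replicate 3 (lowest -0.73 without acquired non-responder replicate 5).

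Leaving out 1 library gave, as lowest and highest counts in carcinoma cells, 0 and 55 for lenvatinib responders, 207 and 1001 for acquired non-responders against responders, 0 and 1 for partial responders, and 0 in every other comparison. In macrophages they were 0 and 740, 24 and 770, 0 and 9 for anti-PD-1 and 0 and 1 for CSF1R inhibition. In endothelial cells they were 4 and 16, and 0 and 1, in T cells 0. List calls were 113 and 142. Share differences ran from -1.22 to -0.846 (endothelial cells, lenvatinib responders), -0.151 to -0.0157 (endothelial cells, acquired non-responders against responders), 9.16 to 14.0 (T cells, lenvatinib responders), -15.5 to -5.88 (macrophages, lenvatinib responders). They ran from 4.12 to 11.7 and -6.67 to 0.899 (T cells, combination against untreated and against lenvatinib; the latter turned without combination replicate 4), 4.50 to 10.5 (T cells, anti-PD-1 responders), -3.19 to 7.09 (macrophages, anti-PD-1 responders, with -1.56, -1.98 and -1.39 among the turned values), 0.449 to 2.90 (T cells, partial responders) and -19.0 to -9.38 (macrophages, CSF1R inhibition).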

Other observations

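The test of the hypothesis in this part was chosen after its pattern was seen. Several genes were on in carcinoma cells of some tumours and off in others. Of 34 libraries, Rhox6 was under 2 CPM in 10 and Gstp2 in 13, and all 10 were among the 13; Rhox5 was under 2 CPM in 23, Cox4i2 in 18 and Snhg11 in 17. Gstp2 stood between 37.5 and 188 CPM in untreated tumours and between 37.3 and 139.97 CPM in acquired non-responders, but between 0 and 1.23 CPM in lenvatinib 2-week responders, and anti-PD-1 2-week non-responders held 0.395 to 1.20 CPM. Which tumours share an origin is not in the labels, and the overlap of these genes was not tested.

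Neutrophils of lenvatinib 2-week responders held more Vegfa RNA than those of untreated tumours, at 366 ± 135 against 81.5 ± 43.4 CPM (n = 4 each), and those of combination responders 329.9 ± 74.99 CPM (n = 4), while acquired non-responders stood at 101 ± 59.5 CPM (n = 6). Without the 3 neutrophil clusters whose leading genes are mostly those of a macrophage cluster (38 with 1950 cells, and 39 and 79 led by pancreatic enzyme genes), left out after the data were seen, Vegfa stood at 365 ± 146 CPM in responders, 349 ± 62.4 CPM with the combination and 89.0 ± 42.9 CPM in untreated tumours. Dendritic cells showed 53.6 ± 26.4 against 14.99 ± 7.18 CPM. Neutrophils made 33.4 ± 28.7% of combination responders against 8.22 ± 3.42% of untreated tumours (exact p = 0.0857, adjusted p = 0.588; 32.7% against 7.68% without those clusters), and NK cells 1.74 ± 0.51% against 3.42 ± 1.53% with lenvatinib alone, lower in 4 of 4 (exact p = 0.0286, adjusted p = 0.514).

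In groups too small for a comparison, neutrophils made 22.1% of the 2-week tumour under CSF1R inhibitor plus anti-PD-1 and 25.0% of the long-term one (20.8% and 2.504% without those clusters), with 10.0% and 16.1% macrophages. The lenvatinib plus anti-PD-1 non-responder (n = 1) held 36.5% macrophages, 10.9% T cells and 0.34% endothelial cells, and the acquired non-responder to anti-PD-1 (n = 1) held 56.2% carcinoma cells and 2.15% T cells. In macrophages of the long-term tumour under both CSF1R inhibitor and anti-PD-1, 89.2% of cells fell into cluster 49, which came almost wholly from this library and is led by pancreatic enzyme genes such as Ctrb1, so the value reflects that RNA.

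A hypothesis on the macrophage hypoxia response under lenvatinib is that cells with intact Vhl respond to a loss of oxygen as vessels regress, while carcinoma cells without Vhl have no further response to give. The mean hypoxia score was higher by 1.06 log2 units in macrophages and by 0.0464 in carcinoma cells (exact p = 0.943). That pattern prompted the hypothesis and so is no test of it. In other classes the score was higher by 0.541 in neutrophils (higher in 2 of 4, and 0.508 without those clusters) and 0.264 in dendritic cells (1 of 4). T cells, which also keep Vhl, differed by only 0.114, so the test does not decide; the macrophage value had an adjusted p of 0.479 over 616 tests of scores. Oxygen was not measured, and an effect of lenvatinib on macrophages themselves stays open.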
